A study of Emberiza melanocephala with 4 samples.

How the data were processed

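RNA was measured in whole blood of wild-caught black-headed buntings in 4 libraries, 1 each of photosensitive and photorefractory birds at ZT10 and ZT14. Per the labels, total RNA was extracted with Tri reagent and libraries were made with standard Illumina protocols. The number of birds behind each library is not given in the sources used here. Per the submitters' processing notes, reads were trimmed with Trimmomatic and quantified with kallisto; versions, read length, and the settings of the transcript assembly are not given in the sources used here.

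The deposited files give, for each library, kallisto's estimated counts (expected counts, not normalized) and TPM (transcripts scaled by length to a fixed total) for one shared set of 585861 transcripts with names in the style of the Trinity assembler. The estimated counts are fractional, and the deposited TPM values sum to the same total in each library. A deposited table of protein matches, with an expectation value (e-value) and a bit score per match as per the file headers, holds 4424604 matches; the search tool and database are not given in the sources used here. Transcript sequences were not used here. Total estimated counts ranged from 6254983 to 7295820 per library, which at 3 counts puts the floor of detection between 0.411 and 0.480 CPM of all counts.

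Each transcript took the name of its best match by bit score at an e-value of at most 1e-05. Of 164552 transcripts with a match, 141629 had a named vertebrate protein as the best match and formed 16412 gene labels. The files hold protein names and no gene symbols. Symbols used here are a reading of those names, from a table of names and symbols written by hand after the files were available and without use of their values. Words such as "-like" and copy numbers were removed from the names, so that a label may merge paralogs or haemoglobin copies, and 1 gene may also be split over labels. Transcripts without a label stayed out of the gene tests. Matches to other organisms were sorted by taxon into classes (yeast, Streptococcus, grasses, haemosporidian parasites, other apicomplexans, trypanosomes and other) and counted apart.

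Estimated counts were summed per label, rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Labels with at least 10 counts in at least 2 libraries (9645) entered a model with state and time as additive terms and TMM scaling, tested by quasi-likelihood (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. With no replicates the model has 1 residual degree of freedom per gene, the difference of the state effect between the 2 times, which stands in for the spread. The fit combines it with a prior shared over genes (median of 4.32 prior degrees of freedom). The common dispersion was 0.175, a coefficient of variation of 41.8%. Values after ± (SE) are the absolute log2 ratio divided by the square root of the test's F statistic. They are not estimated from replicates and can be too narrow at low counts. A test of 2 libraries against 2 compares these libraries and assumes the state difference is alike at both times. Ratios of library pairs are log2 of TMM-scaled CPM with a prior count of 2, with exact conditional binomial 95% intervals. The state by time difference is the time ratio in photosensitive birds minus that in photorefractory birds and has no test. Shares have exact Clopper-Pearson 95% intervals. Bootstrap intervals of list medians resample the members of a list, so they cover spread between genes and not between birds or libraries. A ratio against a library with 0 counts is given as a bound against 3 counts in that library. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.

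Before the data were examined, 25 gene lists were fixed for pathways and cell types that blood could hold: erythroid, T cell, B cell, heterophil, monocyte, thrombocyte, non-blood tissue, interferon response, cytokines and immune signalling, immediate-early, heat shock, antioxidant, glucocorticoid response, hormone receptors, circadian clock, photoperiod and hypophysial, opsins, DNA methylation and chromatin, cell cycle, proteasome, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded, glycolysis and lipid metabolism genes, together with haemosporidian species names. The median log2 ratio of each of the 24 lists with enough members in the test was ranked among 10000 random lists of the same size matched on expression in 20 bins, a description of these libraries and no test. The opsin list is not reported here. Named genes also followed a rule fixed then. It takes, for state and for time, up to 10 called genes per direction with the same direction in both pairs and at least 5 mean CPM, filled as values with the genes whose smaller pair ratio was largest. It adds the 4 members of highest CPM and the 2 of largest change of each list, every tested member of the clock, photoperiod, opsin and chromatin lists, the 5 largest state by time differences per direction, and the 5 genes of highest CPM.

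Other settings tried were DESeq2 size factors, library totals, haemoglobins left out, the DESeq2 1.42.0 Wald test, limma 3.58.1 on log2(TPM + 1), count filters of none or 50, an e-value of at most 1e-20, counts per transcript, a model without the other term, and leaving out each library, which needs a model without the other term. Leaving out a library also leaves 1 library in a state and at a time, so the calls of such fits are a weak check. Alternatives chosen after seeing the data were protein names kept apart, RefSeq names only, and edgeR's revised quasi-likelihood fit. Library totals moved the median of all genes by -0.50 for state at ZT10, -0.23 for state at ZT14, 0.42 for time in photosensitive birds and 0.13 in photorefractory birds. Log2(TPM + 1) moved it by -0.42, 0.03, 0.35 and -0.13; the TMM factors were 1.09 and 1.20 in photorefractory ZT10 and ZT14 and 0.752 and 1.02 in photosensitive ZT10 and ZT14.

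The model was tested on simulated data with the common dispersion of these libraries for every gene and no state by time difference. Genes in these libraries do show such differences, so the simulated rates of calls need not carry over to them. For state it called 0, 10, 36 and 49 of 50 genes changed 2-fold, 4-fold, 8-fold and 16-fold, and 3 of 9445 unchanged genes; for time it called 0, 8, 35 and 49, and 5 unchanged genes. Simulated intervals held the true ratio in 96.7%, 95.9% and 94.9% of cases at mean counts of 20, 200 and 2000. Of 200 simulated unchanged lists of independent genes, 8% lay outside the central 95% of random lists. The simulation did not cover list members that vary together, so 8% is not a rate for the reported lists.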

Results

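Blood RNA of wild-caught black-headed buntings (Emberiza melanocephala), a songbird whose breeding is timed by day length, was sequenced from birds in 2 photoperiodic states. Photosensitive birds can still respond to long days with reproductive growth, and photorefractory birds no longer do. Per the series title, the birds were exposed to a first long day, and blood was taken at zeitgeber time (ZT) 10 and ZT14, given in hours. There were 4 libraries, 1 for each state and time, so no group had replicates. Total estimated counts were 7295820 in photorefractory ZT10, 7269313 in photorefractory ZT14, 6687712 in photosensitive ZT10 and 6254983 in photosensitive ZT14. Of these, 77.7%, 67.5%, 81.7% and 78.1%, in the same order, fell in transcripts that could be given a gene label. P-values here cover these libraries only. They rest on the difference of the state effect between the 2 times, combined with a prior shared over genes, and not on replicates. Intervals on single ratios and shares cover counting error only.

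Haemoglobin was the most abundant product of the blood, as nucleated bird red cells carry much globin RNA. Haemoglobin genes held 25.7% of the labelled counts in photorefractory ZT10 (exact Clopper-Pearson 95% interval 25.6 to 25.7) and 19.0% in photorefractory ZT14 (19.0 to 19.0). They held 41.1% in photosensitive ZT10 (41.1 to 41.2) and 27% in photosensitive ZT14 (27 to 27). The alpha-globin label HBA1, which may pool several copies, stood at 411429 CPM (counts scaled with TMM to a common library size) in photosensitive ZT10 and at 119706 CPM in photorefractory ZT14. Ferritin heavy chain, which stores iron, ranged from 6819 to 17247 CPM. The alpha-D globin HBAD was at 11375 CPM in photosensitive ZT10 and between 4659 and 7833 CPM elsewhere. The photorefractory ZT14 library stood apart: 28.4% of its counts had no protein match (28.3 to 28.4), against 14.3% to 18.5% in the other libraries.

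**Figure D1:**
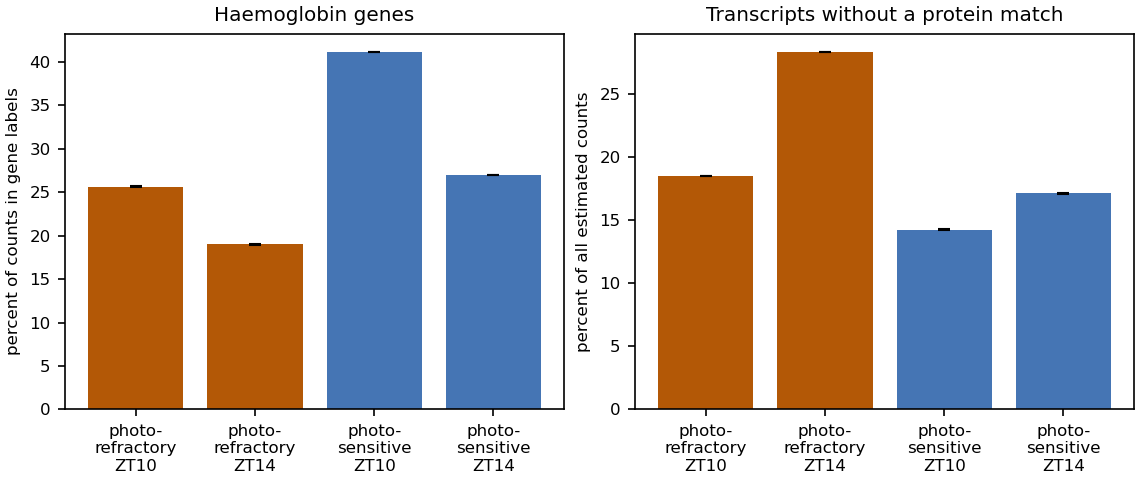
Bars give the percent of labelled counts in haemoglobin genes (left) and the percent of all estimated counts in transcripts without a protein match (right) in each of the 4 libraries. Error bars are exact 95% binomial intervals; haemoglobin was highest in photosensitive ZT10 (41.1%) and unmatched transcripts in photorefractory ZT14 (28.4%).

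The first comparison asked how blood of photosensitive birds differed from that of photorefractory birds at the same times. Red cell genes were higher in the photosensitive libraries: 27 of 33 members of the fixed erythroid list had a higher fitted value, and 26 were higher at both ZT10 and ZT14. The list's median log2 ratio was 0.82, at percentile 100 of 10000 random lists matched on expression. Interferon response genes were also higher (21 of 23 members, median log2 ratio 1.18, percentile 100), 12 of them at both times. Their difference came from ZT14 (median 2.53), with 0.03 at ZT10 (percentile 38.3), negative with library totals (-0.50) and log2(TPM + 1) (-0.72). Genes of heterophils, the bird counterpart of neutrophils, were lower (8 of 10 members, median -1.08, percentile 0.06). This came from ZT14 (median -2.45), with -0.17 at ZT10 (percentile 34.6). The ZT14 values of the interferon and heterophil lists compare with the photorefractory ZT14 library, which stood apart. Thrombocyte genes were lower too (9 of 13, median -0.57, percentile 0.07), at percentile 14.5 with log2(TPM + 1). Only the erythroid list (higher) and the ribosomal protein list (lower) lay outside the central 95% of random lists in the same direction at both times. At ZT10 the ribosomal protein median was near 0 (-0.07, 35 members higher and 40 lower). It lay outside there because the matched random lists lay above 0 (0.003 to 0.32).

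Within the erythroid list, 12 members were called when p-values were adjusted over the list alone (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), all higher in photosensitive birds, and 0 over all genes. They included SLC4A1, the anion exchanger of the red cell membrane, at 6472 and 7509 CPM in photosensitive ZT10 and ZT14 against 3769 and 4294 CPM in photorefractory birds. They also included UROS, an enzyme of haem synthesis, at 6.82 and 15.4 CPM against 1.46 and 2.23 CPM. Among members chosen after their values were seen, ALAS2, which starts haem synthesis in red cells, was higher by 1.05 ± 0.29 (SE) on the log2 scale, with an adjusted p of 0.0434 over the list alone and 0.449 over all genes in edgeR. FECH, which completes haem, was higher by 1.01 ± 0.27, and RHAG, a red cell ammonium channel, by 1.39 ± 0.27. The blood group gene RHD ran the other way, at 54.9 CPM in photorefractory ZT14 and 0.404 CPM in photosensitive ZT14. Scaled to library totals the number called over the list alone was 0, with a count filter of 50 it was 5, and with limma on log2(TPM + 1) it was 1, lower in photosensitive birds. Without the time term 14 were called, 13 of them higher. The number was 0, 1, 0 and 0 when photorefractory ZT10, photorefractory ZT14, photosensitive ZT10 or photosensitive ZT14 was left out, which also drops the time term.

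Medians of white cell and thrombocyte lists were below 0 for photosensitive blood, with the heterophil and thrombocyte lists outside the range of random lists across both times. At ZT10 alone these 2 lists lay inside it and the T cell (-0.72) and B cell (-0.86, percentile 1.73) lists outside. CSF3R, the receptor for the growth factor of granulocytes, was at 34.1 and 19.6 CPM in photosensitive ZT10 and ZT14, against 77.6 and 132 CPM in photorefractory birds. The matrix protease MMP9 had a log2 ratio of -1.21 ± 0.53. ITGA2B, the integrin chain of thrombocytes, had a log2 ratio of -1.53 ± 0.35, and ITGB3, its partner, one of -1.11 ± 0.32, whereas the thrombocyte tubulin TUBB1 was higher by 1.15 ± 0.31. T cell genes were lower in 15 of 19 members (median -0.53, percentile 8.47), with CD8A at 23.9 and 14.5 CPM against 46.6 and 61.1 CPM. Monocyte genes were lower in 7 of 10 (median -0.82, percentile 3.17), for example the receptor CSF1R at -1.50 ± 0.49. B cell genes were lower in 10 of 12 (median -0.56, percentile 17.8), with an exception in the B cell receptor TNFRSF13C (2.32 ± 0.58). None of the members of these 5 lists was called, whether adjusted over the list alone or over all genes.

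Among single genes that differed in the same direction at both times, CD36 had one of the largest ratios in favour of photosensitive birds. This scavenger receptor and fatty acid carrier was at 73.1 and 43.2 CPM in photosensitive ZT10 and ZT14 against 3.73 and 1.20 CPM in photorefractory birds (log2 ratio 4.66 ± 0.50, adjusted p 0.184 over all genes in edgeR and 0.00409 adjusted over the list alone). The lipid droplet protein cell death activator CIDE-A was at 29.5 and 8.08 CPM against 1.30 and 0.515 CPM. The fatty acid-binding protein FABP3 went the other way, at 5.85 and 2.42 CPM against 15.3 and 20.8 CPM (-2.21 ± 0.66). USP18, which removes the interferon-induced modifier ISG15 from proteins, was at 24.6 and 24.9 CPM against 3.08 and 2.40 CPM (3.17 ± 0.53, adjusted p 0.0333 over the list alone in edgeR). Epidermal differentiation-specific protein reached 589 CPM in photosensitive ZT10 and 24.9 CPM in photosensitive ZT14, with at most 0.812 CPM in photorefractory birds. NDUFC1, a subunit of respiratory complex I, was at 25.6 and 12.9 CPM against 0.649 and 1.03 CPM. A mediator subunit of RNA polymerase II transcription, MED23, had a log2 ratio of 2.72 ± 0.41, and syntaxin-18, a membrane fusion protein, one of 3.84 ± 0.70. The protein FAM173A, with 0 counts in photorefractory ZT10, was at least 38-fold higher in photosensitive ZT10 against a floor of 3 counts per library.

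Lower in photosensitive birds was phosphatase and actin regulator 1, with 0 counts in both photosensitive libraries. It was at least 20.9-fold lower at ZT10 and at least 23.5-fold lower at ZT14. Other genes with lower values in photosensitive birds were highest in the photorefractory ZT14 library. T-cell leukemia homeobox protein 1 was at 24.7 and 600.4 CPM in photorefractory ZT10 and ZT14 and at 0.487 and 35 CPM in photosensitive birds. The repressor TGIF2 was at 84.6 and 778 CPM against 2.19 and 58.0 CPM. EGR3, an immediate-early zinc finger factor, was at 12.8 and 146 CPM against 0.244 and 10.3 CPM (-4.26 ± 0.58, adjusted p 0.0117 over the list alone and 0.253 over all genes in edgeR). The cell surface mucin-1 was at 31.2 and 404 CPM against 1.95 and 22.8 CPM. In the 13-gene list of mitochondrially encoded transcripts, 10 of 11 members in the test were lower (median -0.69, percentile 0; -0.20 at ZT10, percentile 4.68, and -1.36 at ZT14), for example MT-ND2 at -1.02 ± 0.33 and MT-ND4 at -0.98 ± 0.33. Ribosomal protein genes were lower in 51 of 75 members (median -0.21, percentile 0), though RPL28 was higher by 1.30 ± 0.38. The list's median was -0.07 at ZT10 (percentile 0.32) and -0.41 at ZT14.

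Metabolic and stress lists went in both directions. Antioxidant genes were higher in 15 of 22 members (median 0.42, percentile 98.7), among them NFE2L2, a regulator of antioxidant genes, at 0.58 ± 0.25. This came from ZT14 (0.63, percentile 99.8), while the ZT10 median of 0.06 (percentile 48.9) turned to -0.47 with library totals and -0.39 with log2(TPM + 1). Heat shock genes were higher in 12 of 18 (median 0.46, percentile 98.2, or 97.0 with log2(TPM + 1)), but at ZT14 the list's median was -0.25. Nuclear genes of oxidative phosphorylation were higher in 50 of 69 (median 0.26, percentile 97.3), a direction that turned with library totals (-0.12) and with log2(TPM + 1) (-0.07). Glycolysis genes were lower in 15 of 19 (median -0.53, percentile 1.67), with LDHA at -0.63 ± 0.34. Glucocorticoid response genes were lower in 10 of 14 (median -0.56, percentile 0.57), with DDIT4, induced by stress, at 915 and 927 CPM in photosensitive ZT10 and ZT14 against 2665 and 1432 CPM. The list's median was -0.12 at ZT10 (percentile 24.0) and -0.61 at ZT14 (percentile 0.76, or 7.28 with log2(TPM + 1)). The immediate-early (-0.33, percentile 2.68), hormone receptor (-0.60, percentile 4.02), cell cycle (-0.55, percentile 4.97), cytokine and immune signalling (-0.63, percentile 8.54) and non-blood tissue (-0.99, percentile 6.70) lists had medians below 0. At ZT10 the immediate-early median was 0.21 (percentile 83.2; -0.32 with library totals and -0.38 with log2(TPM + 1)) and the hormone receptor one 0.02 (percentile 61.4; -0.49 and -0.54), against -0.78 and -1.56 at ZT14. The ZT14 values compare with the photorefractory ZT14 library, which stood apart. The collagen label COL1A1, of the non-blood list, was between 702 and 1090.2 CPM in the 4 libraries and pooled 62 transcripts. Collagen COL1A2, of the same list, was between 1.95 and 27.5 CPM. The proteasome list (median 0.17, percentile 62.0) and the lipid metabolism list (0.07, percentile 86.2) lay within the range of random lists, and their medians turned to -0.22 and -0.32 with library totals. At ZT14 alone the lipid metabolism list lay outside the range (0.39, percentile 99.05), with -0.05 (percentile 58.2) at ZT10.

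Clock and chromatin lists lay within the range of random lists, and the photoperiod list lay below it in the TMM-scaled fit. The 19 circadian clock genes in the test had a median of 0.09 (percentile 68.2), which turned to -0.30 with library totals. At ZT14 the clock gene PER3 was higher in photosensitive blood (1.14, interval 0.93 to 1.37) and at ZT10 lower (-0.77, -0.97 to -0.58). The output factor TEF was at 91.5 CPM in photosensitive ZT14 and at 38.3 CPM in photorefractory ZT14. Of the photoperiod and hypophysial list, 5 members could be tested. Their median was -1.57 (percentile 0.92), or -0.67 with log2(TPM + 1), inside the range (percentile 10.4). At ZT10 it was -0.74 (percentile 13), so only ZT14 lay outside (-1.95, percentile 1.25), against the photorefractory ZT14 library that stood apart. Members included EYA3, a factor induced by long days in the pituitary, at 0.54 ± 0.49 and the thyroid hormone receptor THRA at -2.16 ± 0.85. The 25 DNA methylation and chromatin genes had a median of -0.12 (percentile 33.9). KAT2B, a histone acetyltransferase, was higher by 0.92 ± 0.34, and KDM6A, a histone demethylase, by 0.77 ± 0.31, whereas TET3, an enzyme of DNA demethylation, was lower (-1.45 ± 0.39).

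No gene of 9645 was called for state over all genes in the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. The lowest adjusted p was 0.116. At an unadjusted p below 0.05 there were 1041 genes, 404 higher and 637 lower in photosensitive birds, against 482 that chance would give. The DESeq2 Wald test called 139 genes (32 higher) and limma on log2(TPM + 1) called 164 (14 higher), with 69 called by both. The list-alone call of USP18 was lost without either photosensitive library, that of CD36 without photosensitive ZT10, and that of EGR3 without photorefractory ZT14, photosensitive ZT10 or photosensitive ZT14. These fits also drop the time term, and without it the EGR3 call was lost in all 4 libraries together, while those of USP18 and CD36 were not. Leaving out photorefractory ZT10 gave 150 calls in edgeR, 147 of them lower in photosensitive birds. Across genes, which are not independent replicates, the state ratios at ZT10 and ZT14 had Pearson r = 0.212 and Spearman rho = 0.282, and 61.8% of genes had the same direction.

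**Figure D2:**
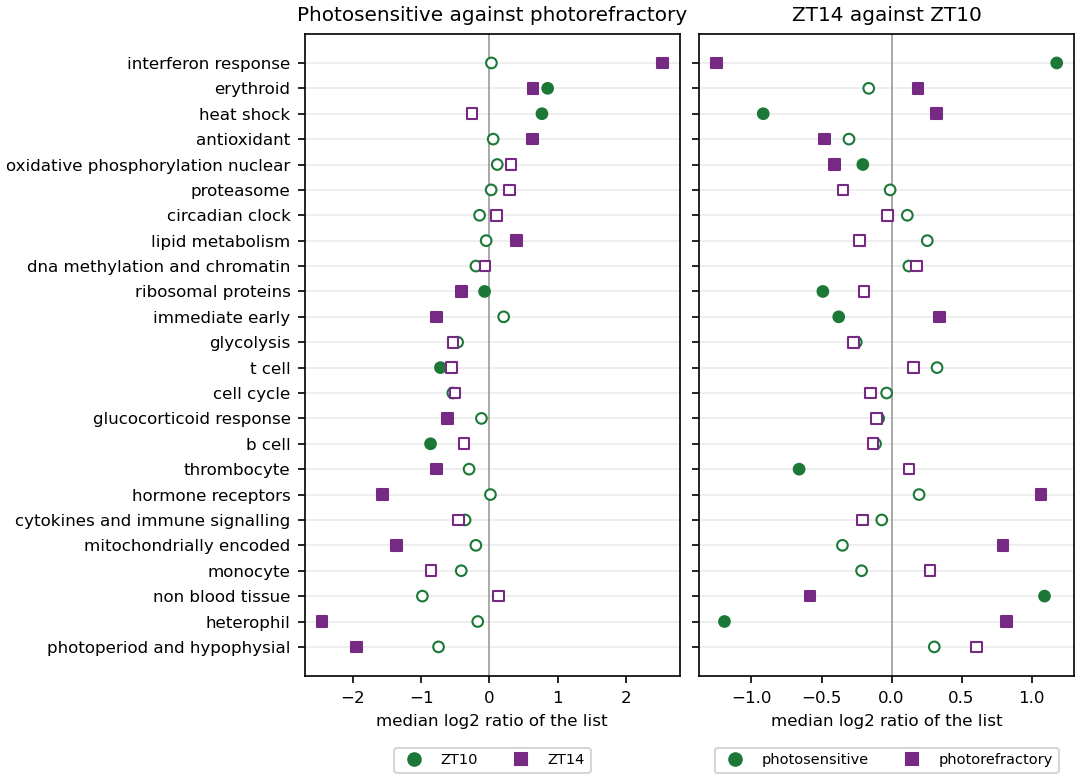
Median log2 ratio of each fixed gene list (horizontal axis) for photosensitive against photorefractory birds at ZT10 and ZT14 (left) and for ZT14 against ZT10 in each state (right). Filled symbols lie outside the central 95% of random lists matched on expression; interferon response genes had a median of 2.53 between the states at ZT14 and of 0.03 at ZT10, the latter negative with library totals and log2(TPM + 1).

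The second comparison asked what differed between ZT14 and ZT10, across both states. Membrane frizzled-related protein, known from the retinal pigment epithelium, and protein FAM167B rose at ZT14. Both calls were lost without the state term, with counts per transcript and in edgeR's revised quasi-likelihood fit (lowest adjusted p 0.0687). The first was at 0.649 and 3848 CPM in photorefractory ZT10 and ZT14 and at 0 and 31.3 CPM in photosensitive birds, the highest of the genes that stood out in photorefractory ZT14. The second was at 0.487 and 505 CPM and at 0 and 12.7 CPM. Ribosomal protein genes were lower at ZT14 in 65 of 75 members (median log2 ratio -0.42, percentile 0), 40 of them in both states. This came from photosensitive birds (median -0.49, percentile 0), while photorefractory birds (-0.20, percentile 39.8) were level with random lists. With log2(TPM + 1) the photosensitive median turned to 0.02 but stayed at percentile 0. Antioxidant genes were lower in 16 of 22 (median -0.38, percentile 0.05) and nuclear genes of oxidative phosphorylation in 54 of 69 (median -0.28, percentile 0), the latter at 0.01 with library totals. Only the list of oxidative phosphorylation lay outside the range in the same direction in each state, and with log2(TPM + 1) it lay inside in photosensitive birds (percentile 14.7).

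The fitted log2 ratio was 12.44 ± 0.51 for membrane frizzled-related protein (adjusted p 0.0112, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and 9.91 ± 0.61 for protein FAM167B (adjusted p 0.0459). The values after ± are calculated back from the test and can be too narrow at such low ZT10 counts. For the first gene these were 4 in photorefractory and 0 in photosensitive birds. With 0 counts in photosensitive ZT10, the rises within photosensitive birds were at least 42.8-fold and at least 17.4-fold. In photorefractory birds the log2 ratios were 11.87 (interval 11.18 to 14.41) and 9.19 (8.47 to 12.30). These were the 2 calls among 9645 genes, and 441 genes had an unadjusted p below 0.05, fewer than the 482 that chance would give. DESeq2 called 127 genes and limma 216, with 99 called by both, and the 2 genes were among the calls of each. Leaving out photorefractory ZT10 or photosensitive ZT10 gave 0 calls, leaving out photorefractory ZT14 gave 14 and leaving out photosensitive ZT14 gave 373. The 2 genes did not reach the count filter without either ZT14 library, so they were not tested there.

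Further genes with higher values at ZT14 in both states, chosen by their values, were each highest in photorefractory ZT14. Leucine-rich repeat-containing protein 4, a synaptic adhesion protein, was at 6.01 and 609 CPM in photorefractory ZT10 and ZT14 and at 1.95 and 56.2 CPM in photosensitive birds. LHX5, a LIM homeobox factor, was at 22.9 and 530.4 CPM and at 2.44 and 52.7 CPM. The aryl hydrocarbon receptor, a ligand-activated transcription factor, was at 14.3 and 559.9 CPM and at 2.44 and 45.9 CPM. Caskin-1, a synaptic scaffold, was at 1.95 and 1056 CPM and at 1.46 and 42.0 CPM. The homeobox factors brain-specific homeobox/POU domain protein 3 and MNX1 and the zinc finger factor PRDM16 had 0 counts in photosensitive ZT10 and were at least 9.40-fold, at least 9.40-fold and at least 11.3-fold higher in photosensitive ZT14. TET3 (2.60 ± 0.40, adjusted p 0.0248 over the list alone and 0.226 over all genes in edgeR), and EGR3 (3.94 ± 0.57, 0.0164 and 0.218) were also higher at ZT14. The list-alone calls of TET3 and EGR3 were lost without photorefractory ZT10, photorefractory ZT14 or photosensitive ZT10, fits that also drop the state term. They were lost without that term in all 4 libraries together as well. The photoperiod and hypophysial list had a median of 0.97 (percentile 98.7), or 0.62 (percentile 89.6) with an e-value of at most 1e-20. It lay inside the range of random lists in photosensitive (0.31, percentile 74.3) and in photorefractory birds (0.61, percentile 89.1). The hormone receptor list had a median of 0.40 (percentile 98.1), with IGF1R, a growth factor receptor, at 2.52 ± 0.70. It lay outside in photorefractory birds (1.07, percentile 99.94) and inside in photosensitive birds (0.20, percentile 81.0).

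Lower at ZT14 in both states was prostaglandin reductase 3, at 28.7 and 1.20 CPM in photorefractory ZT10 and ZT14 and at 66.8 and 1.01 CPM in photosensitive birds. Alpha-2,8-sialyltransferase 8F was at 15.7 and 1.72 CPM and at 195 and 6.06 CPM. The ubiquitin-like protein FUBI, made as a fusion with a ribosomal protein, was at 87.2 and 14.6 CPM and at 399 and 50.9 CPM. Cyclin-G1, a target of p53, had a log2 ratio of -2.41 ± 0.57, and granzyme A, a protease of cytotoxic lymphocytes, one of -1.94 ± 0.57. The abundant ribosomal protein RPL8 was at 2308 and 1376 CPM in photorefractory birds and at 2282 and 1343 CPM in photosensitive birds. Among antioxidant genes the peroxiredoxins PRDX1 (-0.81 ± 0.24) and PRDX4 (-1.54 ± 0.35) and the superoxide dismutase SOD1 (-0.89 ± 0.26) were lower. Heterophil (-0.50, percentile 0.22), glucocorticoid response (-0.40, percentile 0.24), glycolysis (-0.37, percentile 0.30) and cytokine (-0.21, percentile 3.25) lists had medians below 0, the last turning to 0.07 with library totals. The heterophil value averages opposite directions, -1.19 in photosensitive and 0.82 in photorefractory birds, with 2 of 10 members lower in both. The glucocorticoid (-0.09, percentile 32.8, and -0.11, percentile 45.6) and glycolysis (-0.25, percentile 7.8, and -0.27, percentile 7.9) lists lay inside the range in photosensitive and in photorefractory birds. With log2(TPM + 1) glycolysis (-0.02, percentile 9.5) and heterophil genes (-0.17, percentile 2.51) lay inside the range of random lists. The heat shock median of -0.30 (percentile 1.23) turned to 0.06 with log2(TPM + 1). The erythroid median was 0.02 (percentile 99.2), the mitochondrially encoded one 0.12 (percentile 99.1), the interferon one 0.02 (percentile 90.4) and the chromatin one 0.14 (percentile 90.3).

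The third comparison set the time difference of photosensitive birds beside that of photorefractory birds. Interferon response genes moved in opposite directions: 22 of 23 were higher at ZT14 than at ZT10 in photosensitive birds (median log2 ratio 1.18), and 22 of 23 were lower in photorefractory birds (median -1.25). IRF1, a transcription factor of the interferon response, was at 565 and 1632 CPM in photosensitive ZT10 and ZT14 and at 459 and 178 CPM in photorefractory birds. Heterophil genes ran the other way, lower at ZT14 in 10 of 10 members in photosensitive birds (median -1.19) and higher in 8 of 10 in photorefractory birds (median 0.82). These are values with no test, since the 4 libraries leave no residual degree of freedom for such a difference. The photorefractory ratios rest on the ZT14 library that stood apart.

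The interferon-induced IFI27 was at 624 and 1434 CPM in photosensitive ZT10 and ZT14 and at 319 and 60.4 CPM in photorefractory birds. IFIT5, which binds viral RNA, was at 28.3 and 139 CPM and at 19.3 and 2.06 CPM, and the antiviral synthetase OAS1 at 514 and 1046 CPM and at 310.4 and 180.2 CPM. IRF7 followed the list, with a smaller ratio in photosensitive birds (0.39, interval 0.31 to 0.47) and the list's median ratio in photorefractory birds (-1.25, -1.33 to -1.18). LY6E was an exception, at 83.1 and 28.1 CPM and at 91.1 and 79.5 CPM. At ZT10 the list barely differed between the states (median 0.03, negative with library totals and log2(TPM + 1)), and at ZT14 its median was 2.53. GADD45B, a stress-induced immediate-early gene, had the same pattern, at 891 and 2308 CPM and at 916 and 266 CPM. The heterophil calcium-binding protein S100A9 was at 304 and 74.8 CPM in photosensitive birds and at 213 and 402 CPM in photorefractory birds.

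Heat shock genes were lower at ZT14 in 15 of 18 members in photosensitive birds (median -0.92) and higher in 12 of 18 in photorefractory birds (median 0.32). The chaperone HSP90AA1 was at 783 and 258 CPM and at 244 and 667 CPM. Mitochondrially encoded genes had medians of -0.35 and 0.80, the first turning to 0.02 with library totals and 0.06 with log2(TPM + 1), and MT-CO1 was at 339 and 327 CPM and at 301 and 956 CPM. Immediate-early genes had medians of -0.38 and 0.34, the first turning to 0.04 and 0.13 under the same scalings, still outside the range of random lists (percentiles 0.74 and 2.17). Hormone receptor genes had medians of 0.20 and 1.07, with the retinoid receptor RXRG at 12.9 and 15.8 CPM and at 30.7 and 154 CPM. The melatonin receptor MTNR1B, with 0 counts in photosensitive ZT10, reached 2.63 CPM in photosensitive ZT14 and 16.6 CPM in photorefractory ZT14. Thrombocyte genes had medians of -0.66 and 0.12, the first turning to 0.09 with log2(TPM + 1), still outside the range of random lists (percentile 1.82). The non-blood tissue list had medians of 1.09 and -0.58, the first being 0.64 with the member at 0 counts set to its bound.

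Several clock genes differed between the states in their direction over time. The clock list as a whole had a state by time median of 0.45 (percentile 94.5), within the range of random lists, with 14 of 19 members above 0. PER3 was at 72.6 and 101 CPM in photosensitive ZT10 and ZT14 and at 124 and 45.5 CPM in photorefractory birds. NR1D2, a repressor in the clock loop, was at 79.0 and 129 CPM and at 117 and 77.2 CPM. PER2 was higher at ZT14 in photosensitive birds (0.54, interval 0.37 to 0.71) and level in photorefractory birds (-0.01, -0.15 to 0.13). BHLHE40 and BHLHE41, repressors that act on clock genes, were higher in photorefractory ZT14, at 26.6 and 27.8 CPM, with at most 7.8 CPM elsewhere. CLOCK had lower values at ZT14 in both states, at 161 and 97.6 CPM and at 111 and 101 CPM. SIRT1, a deacetylase linked to the clock and metabolism, was level in photosensitive birds (702 and 667 CPM) and lower at ZT14 in photorefractory birds (894 and 345 CPM). The DNA methyltransferase DNMT3A was at 2.44 and 1.62 CPM and at 2.92 and 15.3 CPM. Across genes the time ratios of the 2 states were nearly unrelated, with Pearson r = 0.127 and Spearman rho = -0.008, and 49.0% of genes had the same direction. At least 2-fold differences at ZT14 were found in 1007 genes higher and 929 lower in photosensitive birds, and in 1267 higher and 699 lower in photorefractory birds.

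**Figure D3:**
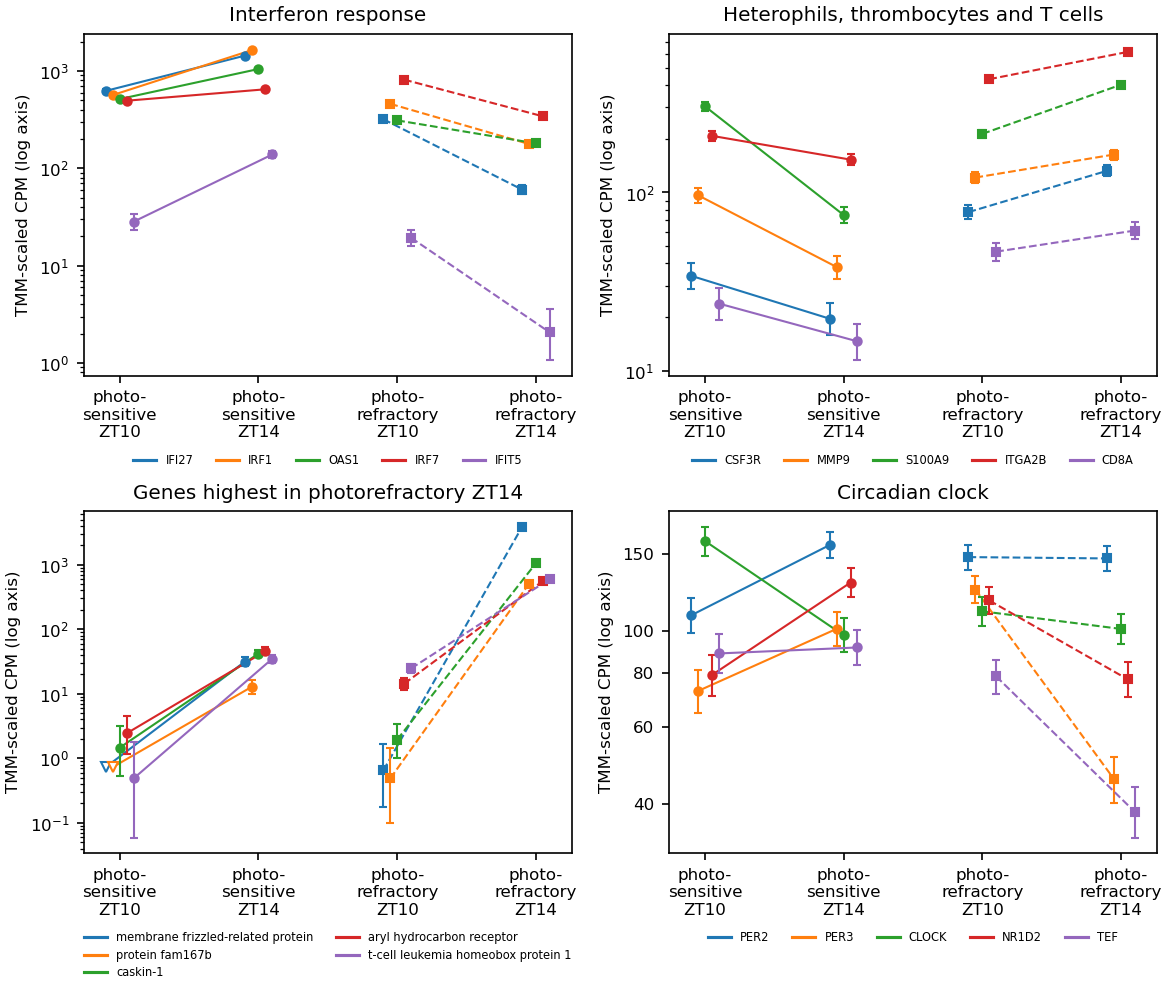
TMM-scaled CPM (vertical axis, log scale) of genes named in the text, with circles and solid lines for photosensitive and squares and dashed lines for photorefractory libraries, and 95% Poisson intervals of the counts. Open triangles stand at the floor of 3 counts for libraries with 0 counts; IRF1 reached 1632 CPM in photosensitive ZT14 and 178 CPM in photorefractory ZT14.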

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

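The tests of a changed white cell share and of a haemosporidian infection were chosen only after the result was seen. Lists are given here where their median time ratios had opposite signs in the 2 states and both lay outside the range of random lists, and single genes where the state by time difference was among the 5 largest per direction. None of these differences was tested, since each state and time has 1 library.

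Interferon response genes had a state by time median of 2.20 on the log2 scale: higher at ZT14 in photosensitive birds and lower at ZT14 in photorefractory birds. A changed share of white blood cells would move white cell lists alike, but the highest state by time median among them was 0.89 (B cell), below the bootstrap interval of the interferon median (1.64 to 2.90), which argues against it as the whole cause. For the higher values in photosensitive ZT14, infection with a haemosporidian blood parasite is a candidate explanation. There, 24 counts matched haemosporidian proteins (Poisson interval 15.4 to 35.7, over 11 transcripts), against 4, 0 and 2 in photorefractory ZT10, photorefractory ZT14 and photosensitive ZT10. Other apicomplexan matches were instead highest in photorefractory ZT14, with 31 counts (21.1 to 44.0). They had 9, 7 and 2 counts in photorefractory ZT10, photosensitive ZT10 and photosensitive ZT14. Whether such matches stem from parasite RNA or from the assembly was not tested. For the lower values in photorefractory ZT14, the 4 counts in photorefractory ZT10 are too few, so infection and other causes cannot be told apart there. Photoperiodic state, other infections and differences between individual birds stay open as untested. So does whatever set the photorefractory ZT14 library apart, since that library enters the state by time median.

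Heterophil genes had a state by time median of -1.76, heat shock genes one of -1.32, and immediate-early genes one of -0.96. The last turned to 0.06 with log2(TPM + 1), still outside the range of random lists (percentile 0.88). The immediate-early time median in photosensitive birds turned to 0.04 with library totals, still outside the range of random lists (percentile 0.74). It lay inside that range with an e-value of at most 1e-20 (percentile 3.19). The non-blood tissue list had a state by time median of 1.44 over 7 members. Its photosensitive time median was 0.64, inside the range of random lists (-0.76 to 0.89), with the member at 0 counts set to its bound. Its photorefractory one lay inside the range with DESeq2 size factors (percentile 2.55), with library totals and with an e-value of at most 1e-20 (percentile 3.65).

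Single genes with the largest differences were transcription factor SOX-17 (state by time difference -9.67), actin-binding LIM protein 3 (-9.56) and protein FAM222A (-8.57). Actin-binding LIM protein 3 was at 395 CPM in photorefractory ZT14 and at most 2.92 CPM in the other libraries, so its difference rests on that library. Its time ratio in photosensitive birds was -0.73 with an interval of -2.35 to 0.56, which gives no direction. Protein S100-A7 (-8.22) had 0 counts in photosensitive ZT14, where it was at least 80.4-fold lower than in photosensitive ZT10. Fork head domain protein FKD6 (-7.86) had 0 counts in photorefractory ZT10 and was at least 73.0-fold higher in photorefractory ZT14. The differences of these last 2 genes depend on the count added before taking logs and are not bounds. In the other direction were the apoptosis facilitator BCL-2-like protein 14 (8.47), the small GTPase RHOB (6.55), transcription factor ETV7 (6.03), DNA polymerase theta (5.97) and WD repeat-containing protein 66 (5.95), the last at 110.1 CPM in photosensitive ZT14.

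Counts outside the gene labels exceeded the floor of 3 counts in several classes. Matches to yeast reached 15544 CPM of all counts in photosensitive ZT14, with 6492 to 9133 CPM in the other libraries. Matches to Streptococcus reached 798 CPM in photosensitive ZT10, with 160.4 to 183 CPM elsewhere. Matches to grasses reached 676 CPM in photorefractory ZT14 and 512 CPM in photosensitive ZT10, with 5.21 and 25.7 CPM in photorefractory ZT10 and photosensitive ZT14. Haemosporidian matches reached 3.84 CPM in photosensitive ZT14, other apicomplexan matches 4.26 CPM in photorefractory ZT14, and all other organisms together 8832 CPM in photosensitive ZT10. Transcripts without a protein match held 28.4% of the counts in photorefractory ZT14. A trypanosome match had 2 counts in photosensitive ZT10 and 0 in the other libraries. Whether these matches stem from RNA of other organisms or from the assembly was not tested.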

How the results depend on the processing

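The alternatives with protein names kept apart, with RefSeq names only and with the revised quasi-likelihood fit were chosen only after the data were seen. For state, with 0 calls as reported, 0 were also called with DESeq2 size factors, with haemoglobins left out, per transcript, without the time term, with RefSeq names and with the revised fit. Library totals gave 1 call, names kept apart 2, an e-value of at most 1e-20 gave 7, a count filter of 50 gave 10, the DESeq2 Wald test 139, limma on log2(TPM + 1) 164 and no filter 283; from 0% to 23.0% of each were higher in photosensitive birds, apart from 1 of 2 with names kept apart. Leaving out 1 library gave 0 to 150.

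For time, with 2 calls as reported, 2 were called with DESeq2 size factors, with haemoglobins left out and with RefSeq names. Names kept apart gave 5 calls, a filter of 50 gave 12, an e-value of at most 1e-20 gave 28, library totals 33, DESeq2 127, limma 216 and no filter 271, and each of these included the 2 genes. Per transcript, without the state term and with the revised fit the count was 0; the lowest adjusted p was 0.0687 in the revised fit, in a range from 1.03e-34 to 1 over all alternatives. Leaving out 1 library gave 0 to 373. The cause of these differences was not tested.

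No reported direction with a call reversed. Of 235 named genes, 30 state and 40 time ratios without a call lay on the other side of 0 with library totals. The numbers were 29 and 38 with limma on log2(TPM + 1), and 2 and 0 with DESeq2 size factors. Library totals and log2(TPM + 1) also move the median of all genes, which changes signs of ratios near 0. Of 72 list medians outside the range of random lists, 71, 71, 65 and 57 stayed outside with DESeq2 size factors, library totals, the stricter e-value and log2(TPM + 1), and 0, 5, 0 and 11 changed sign. Depth limited genes near 10 counts, and 1 library per group limited every comparison.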

Other observations

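The tests of sequencing depth and of a lower share of white cells and thrombocytes were chosen only after the result was seen; those of nervous tissue RNA, evenly spread genomic DNA and the haemoglobin share were written before.

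Some genes stood out in a single library and were chosen after their values were seen. In photosensitive ZT10, the mitochondrial tRNA modification GTPase GTPBP3 was at 225 CPM and the ribosomal stalk protein RPLP1 at 159 CPM, with at most 13.9 CPM in any other library. In photorefractory ZT10, 11-cis retinol dehydrogenase, an enzyme of the visual cycle, was at 178 CPM, with 4.98 to 19.6 CPM elsewhere. In photosensitive ZT14, DNA polymerase delta subunit 4 was at 53.1 CPM, with at most 4.63 CPM elsewhere. In photorefractory ZT14, lin-28 homolog A, an RNA-binding protein of stem cells, was at 1483 CPM and growth/differentiation factor 11 at 987 CPM, with at most 59 CPM of either elsewhere. Of 85 labels with homeobox in their name, 80 were higher in photorefractory ZT14 than the mean log2 CPM of the other 3 libraries, with a median of 31.4 CPM there and of 2.92, 2.92 and 3.44 CPM in photorefractory ZT10, photosensitive ZT10 and photosensitive ZT14.

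In photorefractory ZT14, 1.69% of the 9645 tested genes were at least 8-fold above each other library, 19 of them named homeobox, against 2, 7 and 2 such genes in photorefractory ZT10, photosensitive ZT10 and photosensitive ZT14. RNA from nervous tissue would bring its abundant transcripts along. In that library 18 neuronal and glial transcripts had a median of 1.12 CPM, 0.00966 of the 116 CPM of these genes. Choosing the genes for high values there lowers this ratio, so it does not decide whether some nervous tissue RNA was present. The median of the 18 was lower in photorefractory ZT10 (0.649 CPM), photosensitive ZT10 (0.487 CPM) and photosensitive ZT14 (0.808 CPM). Neurofilament medium polypeptide (51.0 CPM) and synapsin-1 (34.5 CPM) were also highest in photorefractory ZT14. Others were not. Neurofilament light polypeptide, the most abundant of the 18, was at 330 CPM there and at 585 and 447 CPM in photosensitive ZT10 and ZT14. Neuroserpin was lowest in photorefractory ZT14 (16.3 CPM). Genomic DNA spread evenly would cover unmatched transcripts as much, but these genes had 24.7 times their median counts per kb. Choosing the genes for high counts there raises this ratio, so it does not decide on evenly spread DNA. A deeper library is argued against by a total 0.996 of the highest other. Unspliced RNA and unevenly spread DNA such as GC-rich stretches stay open, since transcript sequences were not used here. Some nervous tissue RNA, evenly spread DNA and a difference between birds stay open too. Photoperiodic state and time were not separated from this single library, and no biological explanation was tested.

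Markers of blood cell types differed between the states. The share of counts taken by haemoglobins could lift other red cell genes only through scaling, which would move random lists alike, but the 29 other red cell genes had a median of 0.82 (24 higher, random lists -0.06 to 0.46). This gap to random lists argues against haemoglobins as the whole cause. With library totals, which lowered the median of all genes from -0.07 to -0.45, the median was 0.44 (random lists -0.44 to 0.07). That shift is shared by all genes, so it is no separate check. For a lower share of white cells and thrombocytes in photosensitive blood, the 5 list medians lay within 0.69 of each other at ZT10, but 4 bootstrap intervals covered 0, so it and no difference cannot be told apart there. At ZT14 they lay 2.08 apart, with heterophil genes at -2.45 (bootstrap interval -2.73 to -1.55) and B cell genes at -0.37 (-0.54 to 1.04). For this pair of libraries that argues against one shared cause. The intervals cover spread between list members only, and photorefractory ZT14 stood apart. A change in heterophils alone, a change in red cell number, and photoperiodic state stay open as untested.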
